A study of Sus scrofa with 12 samples.

How the data were processed

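The labels describe IPEC-J2 cells from the pig, kept in DMEM/F12 medium with serum and given 0 or 25 µM OAA for 24 h, with 3 numbered replicates per treatment. Per the labels, total RNA was broken into fragments of about 100 nt and divided into an input part and a part bound by an m6A antibody, and random-primed libraries were sequenced by Illumina, giving 12 libraries in 4 groups of 3. Per the submitters' processing notes, Bowtie2 and HISAT2 were used. Their versions and roles, and the genome build, are not given in the sources used here.

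A table of merged peaks and a gene expression table were used. Per the file headers, the peak table holds read counts of each library in each merged peak, one log2 ratio per treatment, a p-value and an adjusted p-value of the authors for the difference between the treatments. A fold value given here for the authors' deposited table is 2 raised to its log2 ratio. The deposited gene table holds FPKM of 6 libraries, whose codes belong to the libraries labelled IP. All columns of single libraries were matched to a sample (0 unmatched). The peak table has 29011 entries for 25055 distinct peaks, since a peak is listed once for each gene it touches. Each peak was used once, with counts that were the same in all its entries. Of these peaks, 21450 lie under 1 gene and 3605 under several, 124 have no count, 768 are lncRNA peaks and 24287 mRNA peaks. The median span is 300 bp, and 1359 peaks span over 10000 bp, up to 272463 bp. The peaks lie on 11422 genes, 9325 of them with a peak of their own and a median of 2 such peaks. Listed peak starts were 1 below the gene start in 717 peaks and equal to it in 8, so starts were taken as 0-based and are printed here as 1-based positions.

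The gene table holds 20889 genes, 20299 with Ensembl identifiers and 590 assembled ones named MSTRG, and 4727 of them are at 0 in all 6 libraries. Of 20778 Ensembl identifiers in either table, 14683 took their symbol from the reference table, 1079 from the deposited table alone, and 5016 have none. For 156 identifiers the tables gave different symbols, and that of the reference was kept.

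The labels and the codes of the libraries disagree about which libraries are the antibody part. Groups follow the labels. The peak ratio was turned, after the counts had been seen, to labelled input over labelled IP, which is the direction of the deposited log2 ratios and opposite to the contrast planned before the data were examined. Turning it changes signs only.

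Counts were compared with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, default filtering by expression) in R 4.3.3, and features with a Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons planned before the data were examined were OAA against CON in the libraries labelled input, the peak ratio in CON and in OAA, its change between the treatments, and OAA against CON in the libraries labelled IP. For the labelled-input comparison, counts of peaks under 1 gene were summed per gene; the others were made per peak. TMM sets the typical peak to 0, so peak ratios are relative. The comparison of FPKM was added after the files had been seen, with limma 3.58.1 (trend) on log2(FPKM + 1) for genes with at least 1 FPKM in 3 libraries. On that scale differences of genes with low FPKM are understated. FPKM alternatives planned for the labelled-input comparison were run for this added comparison instead, because of the library codes.

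Lists were tested with camera, in limma, on voom or log2(FPKM + 1) values with a preset correlation of 0.01, adjusted over the 20 lists. They were m6A machinery, proteasome, fatty acid uptake and triglyceride assembly, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation and lipolysis, aryl hydrocarbon receptor targets, NRF2 targets, integrated stress and unfolded protein response, interferon-stimulated genes, NF-kB inflammatory genes, cell cycle, p53 targets, hypoxia and glycolysis, tight junction and adhesion, growth factor and Hippo response, short-lived transcription factor mRNAs, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, and mitochondrially encoded mRNAs. These lists and markers of 7 cell types were fixed before the data were examined.

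Genes are named by a rule fixed at the same time. It takes the features with the largest differences in each direction among those called, with at least 5 CPM in the higher group, a symbol and no overlap between the groups, 5 per direction for peak ratios and 10 elsewhere. Where fewer than 5 features pass, it takes the 10 with the smallest p as not passing. It adds up to 4 members with the smallest p from each list called or holding called members, of which the text prints a part, and always YTHDF2, PSMD3, METTL3, METTL14, FTO and ALKBH5. Some items that the rule selects, among them the peak that DESeq2 called for the change of the ratio, are not reported here. Where one side of a ratio had 5 or fewer counts, the ratio is given with an interval from counting error, and where it was 0, a floor of 3 counts per library was used.

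Replicate numbers were checked for pairing on 3427 genes with at least 200 peak counts and 3 FPKM. Deviations from the group mean in the libraries of one number and treatment correlated at -0.15, 0.16 and 0.07 in CON and 0.20, 0.20 and 0.38 in OAA, with the own number highest in 3 of 6. As the protocol in the labels divides each RNA into its parts, a block for the culture was fitted as an alternative for the peak ratio and its change. Between treatments, deviations of like numbers correlated at -0.15, 0.01 and -0.27 in the libraries labelled input and at -0.18, -0.12 and -0.35 in those labelled IP, so these numbers were not treated as pairs.

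Each comparison was tested on simulated data made from fits to these libraries, with changes of 1.5, 2 and 4 times placed in 200 features. These features had a mean of at least 5 CPM, or 5 FPKM in the FPKM comparison. Shares recovered therefore do not cover features below that mean. All 200 changes were placed at once, in a single draw per comparison. Many true changes make the adjusted threshold easier to pass, so shares can be lower where few features change. The tests were written after the fits to the real data. In order of size, the share recovered was 74.6%, 95.5% and 100% for labelled input, 44.8%, 88.1% and 100% for the CON ratio, 55.2%, 88.1% and 100% for the OAA ratio, 20.9%, 74.6% and 97.0% for its change, 61.2%, 80.6% and 100% for labelled IP, and 95.5%, 100% and 100% for FPKM. Of the calls, 8.63%, 6.63%, 6.90%, 7.25%, 8.52% and 5.74% were false, above the nominal 5%. For lists only the FPKM comparison was tested in this way: camera made a call in 1 of 20 null draws and found a list shifted by 0.5 log2 in 20 of 20. Genes were drawn independently of each other, so these draws cannot show how correlation between genes affects list calls. The shift placed was also far larger than the list medians found in FPKM. The 95% interval of a log2 difference reached a median of 0.27, 0.42, 0.44, 0.62, 0.39 and 0.18 to either side in the same order, a fold of 1.20, 1.34, 1.36, 1.54, 1.31 and 1.13.

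Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, blocks, a 2-fold threshold, sums per gene, and each library left out in turn. For lists they were an estimated correlation, fry and the block. The alternatives for FPKM, for sums per gene and for lists with a library left out, and the fit without OAA culture 3, were added after the files had been seen. The 2-fold threshold was planned only for labelled input and the change of the ratio, and fry only for the lists of those comparisons. An estimated correlation and the block were not planned for the lists in FPKM or in OAA. List tests in OAA were themselves not among the planned ones. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.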

Results

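N6-methyladenosine (m6A), the most common internal base modification of mRNA, was mapped by MeRIP-seq, in which RNA fragments bound by an m6A antibody are sequenced beside unselected fragments of the same RNA. The cells were IPEC-J2, an epithelial line from pig small intestine. They were kept for 24 h with 0 µM (CON) or 25 µM (OAA) of a compound that the labels call OAA, in a series whose title concerns 2-oxindole-3-acetic acid, a gut bacterium, lipid accumulation and the proteins PSMD3 and YTHDF2. Each treatment had 3 numbered replicates, called cultures here, each with a library labelled IP and a library labelled input, which made 12 libraries in 4 groups. That both libraries of one number come from one culture was taken from the protocol, and the pairing check did not clearly show it. Nothing in the labels says that the cultures were grown separately, so p-values measure only the spread between these samples, which may be technical.

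Reads counted in the 25055 merged m6A peaks came to 21.9, 16.5 and 23.0 M reads in the CON libraries labelled input and to 21.5, 20.4 and 19.0 M reads in the OAA libraries labelled input. The libraries labelled IP held 4.03, 4.46 and 3.71 M reads in CON and 4.61, 4.51 and 4.36 M reads in OAA. These sums cover peaks alone and are not library totals. The group means were 20.5 ± 3.48 and 20.3 ± 1.22 M reads in the libraries labelled input and 4.07 ± 0.379 and 4.49 ± 0.123 M reads in those labelled IP (CON and OAA, SD, n = 3). Of 24931 peaks with a count, 98.3% in CON and 97.3% in OAA had more reads in the libraries labelled input. Per peak, the log2 ratios of the authors' deposited table had medians of 3.97 in CON and 4.04 in OAA, and across peaks, which are not independent replicates, they followed labelled input over labelled IP with r = 0.971 and r = 0.972. The deposited FPKM values carry the codes of the libraries labelled IP, and over 8981 genes they ranked with those libraries' peak counts at a Spearman rho of 0.580 to 0.608 and with the labelled-input counts at 0.342 to 0.367. Groups are named here by their labels throughout. The "peak ratio" is log2 of labelled input over labelled IP, the direction of the authors' deposited table, and if the titles hold, its sign as a measure of antibody enrichment turns. The values of OAA against CON within one label stay the same either way, but whether they measure transcript level or antibody signal depends on which label holds.

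**Figure D1:**
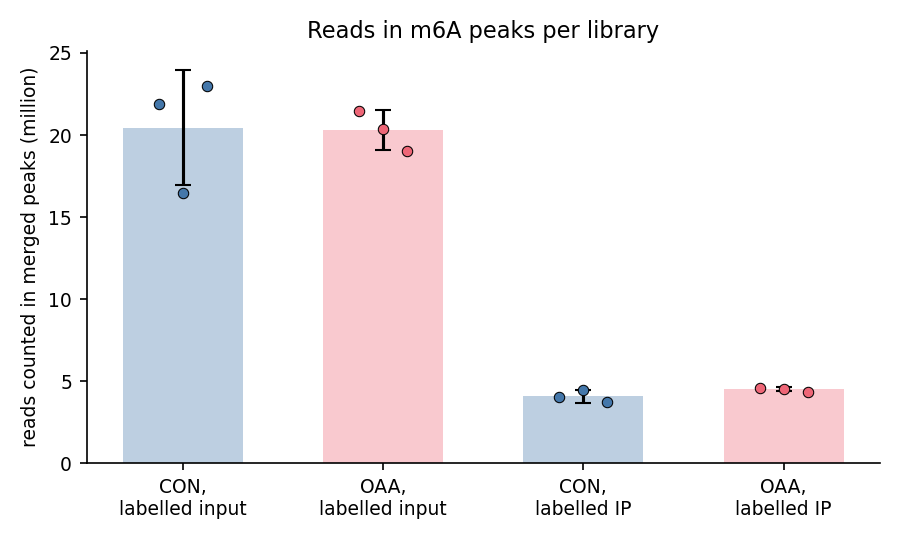
Reads counted in merged m6A peaks per library (y axis, M reads), for CON and OAA libraries labelled input and labelled IP (x axis); bars are means, error bars SD of 3 libraries, and points single libraries. The libraries labelled input hold 16.5 to 23.0 M reads and those labelled IP 3.71 to 4.61 M reads.

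Cell type markers were read as means over the 6 libraries with FPKM, CON and OAA together. Sucrase-isomaltase (SI), a brush-border enzyme of enterocytes, was the highest of the enterocyte markers at a mean of 12.8 FPKM, and 2 of 10 such markers in the table reached a mean of 1 FPKM. FCGBP, a goblet cell mucus protein, stood at 2.98 FPKM and was the 1 of 6 goblet markers at that level. CDH5, an adhesion protein of endothelium, led the endothelial list at 3.78 FPKM, with 3 of 4 markers at 1 FPKM or more. No marker of the other cell types reached 1 FPKM: the highest was NEUROD1 at 0.0518 for enteroendocrine cells, AXIN2 at 0.272 for stem cells, COL1A2 at 0.198 for fibroblasts and CD14 at 0.682 for leukocytes. The 6 markers at 1 FPKM or more were tested between OAA and CON, and none was called. Mitochondrial transcripts, a gauge of RNA composition, took 11.6 ± 0.331% of FPKM in CON and 11.7 ± 0.569% in OAA (SD, n = 3). Of the reads in peaks they took 0.294 ± 0.0436% and 0.303 ± 0.0659% in the libraries labelled input, and 1.02 ± 0.0336% and 1.05 ± 0.0543% in those labelled IP (CON and OAA, SD, n = 3).

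Whether 24 h of OAA altered transcript levels was examined in the deposited FPKM values, which belong to the antibody part if the titles hold. No single gene was called between OAA and CON by limma among genes with at least 1 FPKM in 3 libraries. YTHDF2, an m6A reader that speeds decay of its target mRNAs, stood at 29.8 ± 2.11 FPKM in CON and 27.2 ± 0.887 in OAA, and PSMD3, a subunit of the proteasome's regulatory particle, at 109 ± 0.563 and 108 ± 10.0 (SD, n = 3). The methyltransferase subunits METTL3 and METTL14 stood at 7.31 ± 0.241 and 12.6 ± 0.0462 in CON, and at 7.90 ± 0.196 and 12.5 ± 1.82 in OAA. The demethylases FTO and ALKBH5 stood at 8.91 ± 0.394 and 25.8 ± 1.78 in CON, and at 9.67 ± 0.414 and 26.3 ± 0.648 in OAA. Differences of these 6 genes on the log2(FPKM + 1) scale lay between -0.12 for YTHDF2 and 0.11 for FTO, each with an adjusted p of 1.00 by limma.

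**Figure D2:**
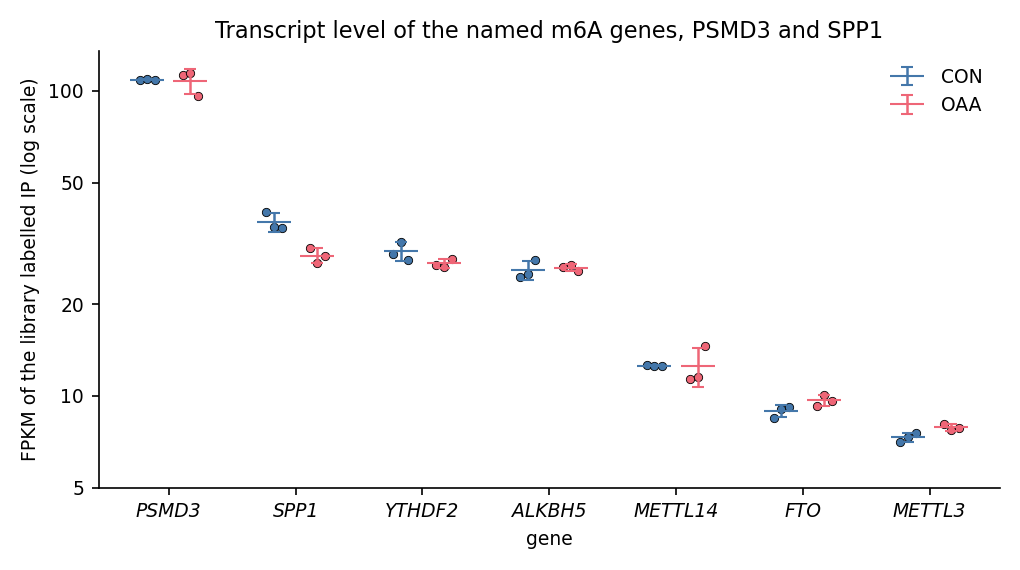
FPKM of the libraries labelled IP (y axis, log scale) for PSMD3, YTHDF2, 4 m6A writer and eraser genes and SPP1 (x axis), in CON and OAA; points are libraries, horizontal lines means and error bars SD of 3. SPP1 lies at 37.1 ± 2.58 in CON and 28.8 ± 1.62 in OAA, and YTHDF2 at 29.8 ± 2.11 and 27.2 ± 0.887.

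Limma called 0 of 10763 genes, with 356 (3.31%) at an unadjusted p under 0.05, or 250 to 1763 with a library left out. The 10 genes with the smallest p did not pass (adjusted p = 1.00). Lower values in OAA were found for PIH1D2 (log2 -0.55), GSTA1 (-0.44), a glutathione transferase that clears electrophiles, TRIM2 (-0.42), PTBP2 (-0.36), RBPJ (-0.36), the nuclear partner of Notch, SPP1 (-0.35), the secreted phosphoprotein osteopontin, and RDH10 (-0.28), a retinol dehydrogenase. Higher values were found for the assembled gene MSTRG.13397 (0.34), DHDH (0.31) and MRPS25 (0.25), a mitochondrial ribosomal protein. SPP1 went from 37.1 ± 2.58 to 28.8 ± 1.62 FPKM and GSTA1 from 20.1 ± 2.08 to 14.5 ± 1.08 (SD, n = 3). The 95% interval of the log2 difference reached a median of 0.18 to either side over genes. In simulated data of the same size limma recovered 95.5% of 1.5-fold changes, placed only in genes at or above the simulation's minimum mean FPKM. Without the minimum on FPKM, MSTRG.12802, a gene outside the naming rule and named after its value was seen, was called at -0.84 (adjusted p = 0.0292). It had 0.803, 0.919 and 0.67 FPKM in CON and 0 in each OAA library. The size of its difference therefore depends on the 1 added before the logarithm.

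Among the 20 gene lists set against these FPKM values, 5 had members that lay higher in OAA than other genes did by camera, each by under 0.05 log2 at the median. None of the 5 calls held with an estimated correlation, where adjusted p = 0.940 with an estimated correlation for the stress list and 0.996 for the others. Cytosolic ribosomal protein genes had 61 of 69 members above 0 (median 0.04, adjusted p = 4.32e-07), with RPL23A at 0.09 and RPL35 at 0.10. Nuclear-encoded subunits of oxidative phosphorylation had 40 of 53 above 0 (median 0.02, adjusted p = 0.0102), with UQCRH of complex III at 0.10. Targets of the integrated stress and unfolded protein response had 16 of 23 above 0 (median 0.03, adjusted p = 0.0180). Among these were HERPUD1, a factor of endoplasmic reticulum degradation, at 36.3 ± 1.46 FPKM in CON and 40.7 ± 0.357 in OAA (SD, n = 3), the chaperone HSPA5 (log2 0.09), the stress factor DDIT3 (0.17) and, below 0, the lipoprotein receptor VLDLR (-0.12). Hypoxia and glycolysis genes had 15 of 22 above 0 (median 0.04, adjusted p = 0.0260), with the glycolytic enzymes GAPDH and ENO1 both at 0.11 and the secreted peptide ADM at -0.15. Cholesterol synthesis genes had 16 of 23 above 0 (median 0.04, adjusted p = 0.0332), with FDFT1, the squalene synthase, at 38.3 ± 1.22 FPKM in CON and 42.7 ± 0.582 in OAA (SD, n = 3), INSIG1 at log2 0.09 and HSD17B7 at -0.12. Fatty acid synthesis genes (median 0.00, adjusted p = 0.818) and genes of fatty acid uptake and triglyceride assembly (median -0.02, adjusted p = 0.856) were not called, nor were targets of the aryl hydrocarbon receptor, a sensor of indole compounds (median -0.05, adjusted p = 0.818). No member of any list was called over all genes, and 0 were called adjusted over the list alone. The number of called lists fell to 0 without OAA library 1, to 1 without CON library 1 or CON library 2, and to 3 without OAA library 2 or OAA library 3. OAA library 3 stood apart from the other OAA libraries: the ribosomal list had a median difference from CON of 0.09 in OAA libraries 1 and 2 and of -0.06 in library 3, and the oxidative phosphorylation list had 0.07 and -0.06.

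The libraries labelled input were compared next, from peak counts summed per gene. Their differences are those of transcript level if the titles hold, and of antibody signal if the titles are exchanged. Again no single gene was called by edgeR, and YTHDF2 differed by -0.03 ± 0.05 and PSMD3 by 0.11 ± 0.07 (log2, OAA over CON, SE). SPP1, lower in OAA in the FPKM values, also lay lower here, at -0.32 ± 0.07 (log2, SE, adjusted p = 0.801). Both libraries of a number were taken to come from the same culture, so the like sign is not an independent observation. METTL14 lay at -0.39 ± 0.13 (unadjusted p = 0.00736, adjusted p = 0.929), while METTL3 and ALKBH5 both lay at 0.07 and FTO at -0.19. CYP1A1, the cytochrome P450 most used as a readout of the aryl hydrocarbon receptor, lay at 0.46 (unadjusted p = 0.0233, adjusted p = 0.929), while the list of such targets had a median of -0.10 with 4 of 7 members below 0 and was not called (adjusted p = 0.913). EdgeR called 0 of 9298 genes, with 453 (4.87%) at an unadjusted p under 0.05, or 354 to 749 with a library left out. Limma-voom called 0, and DESeq2 called 1. That gene, ENSSSCG00000042862, has no symbol in the tables used and also had the smallest p by edgeR, at 0.48 ± 0.09 (adjusted p = 0.432). DESeq2 gave it an adjusted p of 0.00120, and edgeR one of 0.00113 (log2 0.61) without OAA labelled-input library 1.

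The other 9 genes with the smallest p in the labelled-input comparison did not pass either. GPR162, an orphan receptor, had 10 to 17 counts in the CON libraries and 0 in each OAA library. TMEM101 lay at 0.90, the RNA helicase DDX54 at 0.37, LRRC32 at 0.36, WASF3, an actin regulator, at -0.57, TEX28 at 2.18 on 1 to 47 counts, and SGMS2, a sphingomyelin synthase, at -0.26. CALR, a chaperone of the endoplasmic reticulum, lay at 0.21, with 501 ± 27.4 counts scaled to library size (CPM) in CON and 580 ± 17.7 in OAA (SD, n = 3). The 95% interval reached a median of 0.27 log2 to either side, and simulated 1.5-fold and 2-fold changes were recovered at 74.6% and 95.5%. Those changes were placed only in genes at or above the simulation's minimum mean CPM.

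Of the lists in the labelled-input comparison, camera called 3: cholesterol synthesis, stress response and ribosomal proteins. With an estimated correlation none was called (adjusted p = 0.724, 0.584 and 0.947 with an estimated correlation, in this order). Cholesterol synthesis genes lay higher in OAA (median 0.09, 16 of 20 above 0, adjusted p = 0.00747), with MVD at 0.27, INSIG1 at 0.10, ACAT2 at 1.54 ± 0.59 (SE) and HMGCS1 at -0.17. Stress and unfolded protein response targets lay higher too (median 0.08, 16 of 21 above 0, adjusted p = 0.0239), with the chaperone HSP90B1 at 0.18, CHAC1 at 0.17, TRIB3 at 0.14 and SESN2 at -0.29. Ribosomal protein genes lay lower (median -0.09, 55 of 68 below 0, adjusted p = 0.0319), with RPS3A at -0.32, RPL7 at -0.22 and RPL14 at -0.37, against 0.16 for RPS2. Here too OAA library 3 stood apart: the ribosomal list had a median difference from CON of -0.10 in OAA libraries 1 and 2 and of 0.03 in library 3, and the mitochondrial list had -0.12 and 0.41. No member was called over all genes or adjusted over the list alone (0 in each list). The ribosomal list turned without CON labelled-input library 1 (median 0.11, 59 of 68 above 0, adjusted p = 3.57e-09) and was not called without OAA library 1 (0.375) or OAA library 2 (0.0970). The cholesterol list was not called without CON library 1 (0.0715) or OAA library 2 (0.0560), nor the stress list without CON library 2 (0.0658) or OAA library 1 (0.0541), 2 (0.0534) or 3 (0.0665). The number of called lists was 6 without CON library 1, 2 without CON library 2, 1 without OAA library 1 and 0 without OAA library 2.

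Which transcripts carry more or less m6A signal than the typical peak was read from the peak ratio, first in untreated cells. By edgeR, 16242 of 23366 peaks differed from the typical peak in CON, 8166 with a higher and 8076 with a lower ratio. Among the peaks with the highest ratios, a start codon peak of CCM2, a scaffold of vessel integrity (chromosome 18, 50429591 to 50450101), had 1575 counts in the libraries labelled input against 1 in those labelled IP, a scaled ratio of 397 (95% interval 71.1 to 15684). The 5' UTR peak of MACROH2A1, a histone variant (chromosome 2, 137622934 to 137623884), had 1543 against 3, a ratio of 130 (44.3 to 629). Peaks in the stop codon region of CBR1, a carbonyl reductase (chromosome 13, 199658762 to 199658986), the 5' UTR of EMC10, a membrane protein insertion factor (chromosome 6, 55316496 to 55316924), and the coding sequence of FAM50A (chromosome X, 124967893 to 124968194) had ratios of 203 (36.3 to 8011), 76.1 (13.6 to 3015) and 46.6 (12.8 to 386). These intervals, and the floors used for counts of 0, cover counting error only.

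The lowest ratios in CON belonged to peaks listed under several overlapping genes, so the gene behind them is uncertain. A 3' UTR peak under ZNF79 and RPL12 (chromosome 1, 267964640 to 267964864) had a log2 ratio of -5.57 ± 0.18 (SE, adjusted p = 6.13e-18), with 36.9 ± 16.8 CPM in the libraries labelled input and 1758 ± 75.4 in those labelled IP (SD, n = 3). Peaks under ABRAXAS1 and MRPS18C, under BCKDK, ZNF646 and VKORC1, under LAMTOR3 and DAPP1, and under HDGF and MRPL24 had log2 ratios of -5.38, -5.30, -5.16 and -5.02. Scaling by library size alone moved the median of all peaks by -0.34 in CON and -0.29 in OAA, and for m6A enrichment in CON the split of calls from 8166 higher and 8076 lower to 6403 and 10102. Peak ratios are therefore relative to the typical peak under each scaling.

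Summed per gene, 9 of the fixed lists were called in CON by camera with its preset correlation. None of the 9 calls held with an estimated correlation (adjusted p = 0.359 to 0.394 with an estimated correlation). Short-lived transcription factor mRNAs had the highest median ratio of all called lists (log2 0.76, 21 of 27 called higher and 5 lower, adjusted p = 0.000155), led by the circadian repressor BHLHE40 at 2.13, IER5 at 1.70, and KLF4 and KLF5, factors of epithelial differentiation, at 1.61 and 1.35. Ribosomal protein genes had 58 of 66 called lower (median -1.65, adjusted p = 1.22e-11), with RPS4X at -2.42, RPS3 at -1.78 and RPL8 at -1.69. Oxidative phosphorylation subunits had 36 of 40 lower (median -1.57, adjusted p = 8.09e-07), with ATP5F1A of the ATP synthase at -3.18 and UQCRQ at -1.92, against NDUFS6 of complex I at 1.45. All 8 mitochondrially encoded mRNAs measured lay lower (median -1.67, adjusted p = 0.000155), COX3 at -2.22 and CYTB at -1.72 among them. Cell cycle genes had 21 of 24 lower (median -1.47, adjusted p = 9.39e-06), with the topoisomerase TOP2A at -2.14 and the ribonucleotide reductase RRM2 at -1.68. Proteasome subunits had 22 of 24 lower (median -1.37, adjusted p = 4.65e-05), with ADRM1 at -1.84 and PSMD3 at -1.56. Fatty acid synthesis genes had 8 of 12 lower (median -0.89, adjusted p = 0.00795): the desaturase SCD at -1.82, the lipogenic regulator SREBF1 at -1.51, fatty acid synthase FASN at -1.50 and FADS1 at -1.27. Hypoxia and glycolysis genes had 12 of 18 lower (median -0.94, adjusted p = 0.0214), with ENO1 at -1.92 and PKM at -1.55. Tight junction and adhesion genes had 13 of 18 lower (median -0.86, adjusted p = 0.0214), with plakoglobin JUP at -1.76, E-cadherin CDH1 at -1.24 and TJP1 at -1.06. Adjusted over the list alone, these counts were the same for the called lists except that 4 ribosomal protein genes in place of 3 were called higher.

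**Figure D3:**
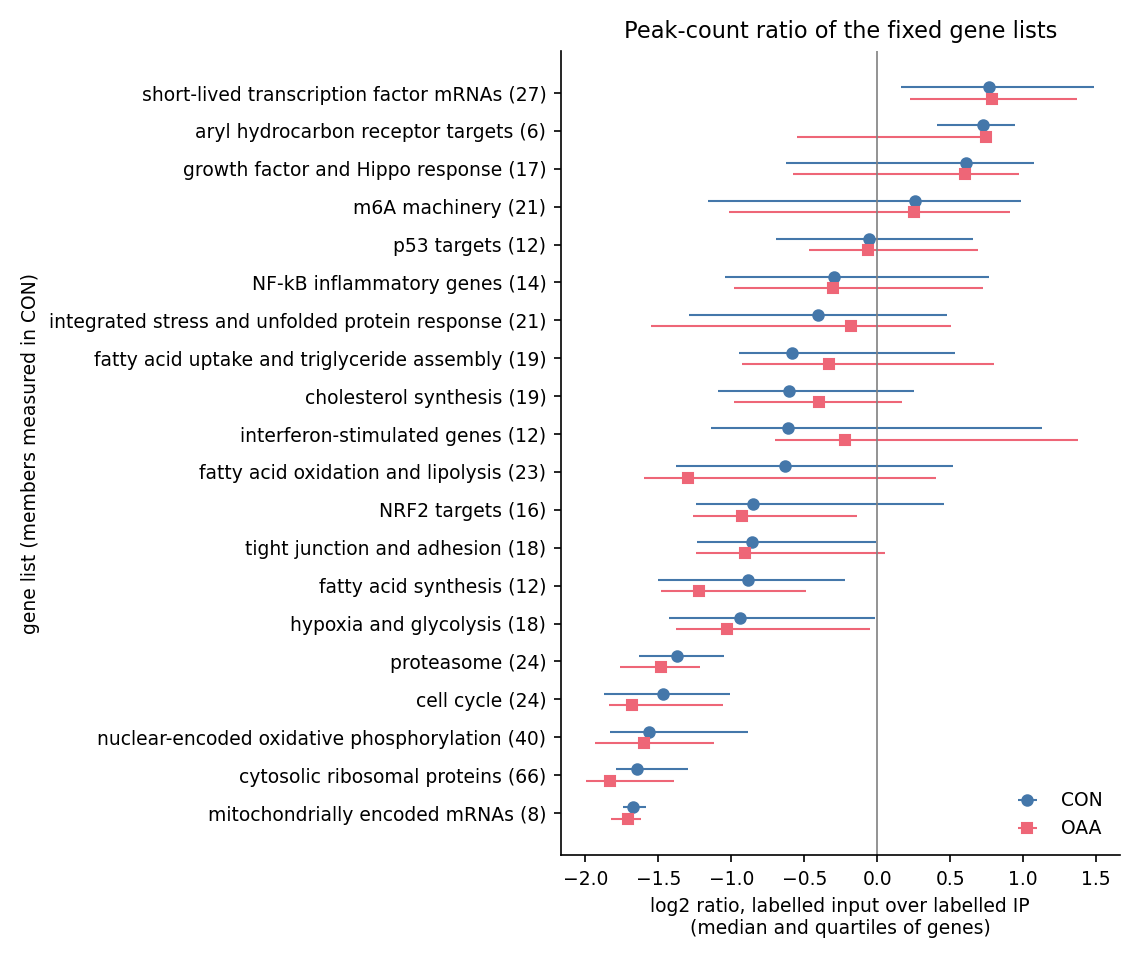
Median log2 peak ratio (labelled input over labelled IP, x axis) of the genes of each of the 20 lists (y axis) in CON and OAA, with lines from the lower to the upper quartile of genes. Short-lived transcription factor mRNAs lie at 0.76 in CON and 0.79 in OAA, and ribosomal protein genes at -1.65 and -1.83.

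The remaining 11 lists in CON held called genes in both directions and were not called as lists. The m6A machinery had 11 of 21 genes called higher and 9 lower, or 11 and 10 adjusted over the list alone, with the writer adaptors RBM15 and RBM15B at 1.65 and 1.42, the reader YTHDF1 at 1.39 and HNRNPC at -1.56; its median was 0.26 and its mean -0.03. Fatty acid uptake and triglyceride assembly had 5 higher and 10 lower of 19, with the acyltransferases AGPAT3 at 1.47 and GPAT3 at -1.81 and the acyl-CoA synthetase ACSL3 at -1.79. Cholesterol synthesis had 6 higher and 12 lower of 19 (EBP 1.80, INSIG1 1.04, IDI1 -1.90). Fatty acid oxidation had 4 higher and 11 lower of 23 (ETFDH -2.09, HADHA -1.21). Aryl hydrocarbon receptor targets had 5 higher and 1 lower of 6 (AHR 0.98, TIPARP 0.83, NQO1 -1.33), and NRF2 targets 3 higher and 10 lower of 16 (SRXN1 1.64, the ferritin FTH1 -1.20). Stress and unfolded protein response targets had 7 higher and 11 lower of 21 (ATF3 1.45, HYOU1 -1.64), interferon-stimulated genes 5 and 5 of 12 (IFIT5 2.08), NF-kB inflammatory genes 5 and 6 of 14 (RELB 1.57, ICAM1 1.05), p53 targets 4 and 4 of 12 (the apoptosis gene BBC3 2.35), and growth factor and Hippo response genes 10 and 6 of 17 (the kinase LATS2 1.93, the phosphatase DUSP1 1.27).

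Per culture, the short-lived transcription factor list lay above the ribosomal list in all 6. Its median ratio was 0.69 to 0.77 over the 6 cultures. That of the ribosomal list was -1.17 in CON culture 1, -1.92 and -1.98 in CON cultures 2 and 3, -2.04 and -1.90 in OAA cultures 1 and 2, and -1.56 in OAA culture 3.

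**Figure D4:**
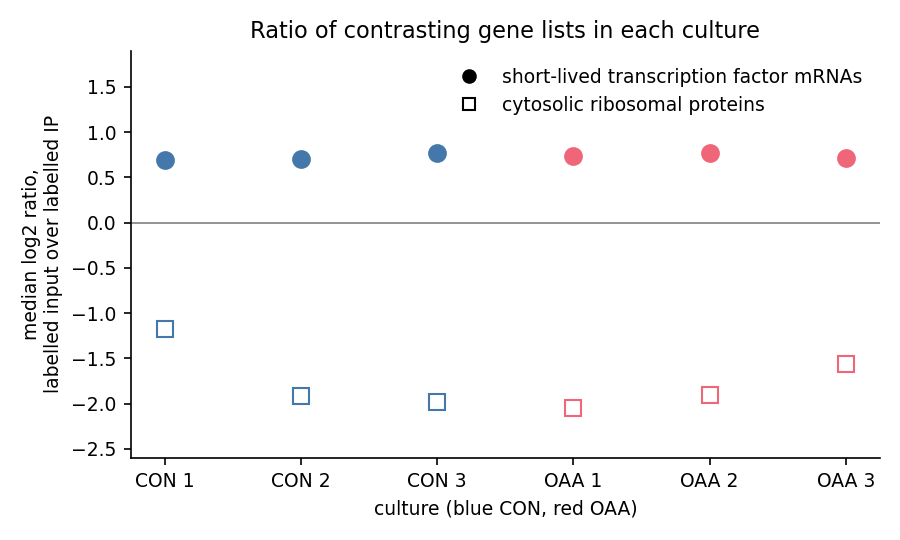
Median log2 peak ratio (y axis) of short-lived transcription factor genes (filled circles) and ribosomal protein genes (open squares) in each culture (x axis; CON blue, OAA red). The difference of the medians is smallest in CON culture 1, at 1.86, and largest in OAA culture 1, at 2.78.

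YTHDF2 and PSMD3, named in the study's title, and the m6A writer and eraser genes of the naming rule carried ratios of both signs. Summed per gene, each kept its sign between untreated and treated cells. Summed over its peaks, YTHDF2 had a log2 ratio of 1.07 ± 0.06 in CON and 1.12 ± 0.07 in OAA (SE, adjusted p = 6.19e-12 and 3.33e-10). ALKBH5 lay at 1.00 and 1.07, FTO at 0.68 and, not passing in OAA (adjusted p = 0.0970), at 0.27. PSMD3 lay at -1.56 and -1.48, METTL3 at -1.19 and -1.29, and METTL14 at -1.16 and -1.57. Of the YTHDF2 peaks, all on chromosome 6, that at 85722846 to 85723795 in the coding sequence had the highest ratio (1.70 in CON and 1.74 in OAA), followed by its coding sequence neighbour at 85722321 to 85722720 (0.72 and 0.74). The stop codon peak at 85746569 to 85746793 lay at -0.29 (adjusted p = 0.106) and -0.49 (adjusted p = 0.00657), and the start codon peak at 85716967 to 85718090 at -0.53 (adjusted p = 0.0313) in CON and, not passing, at 0.25 in OAA. On chromosome 12, ALKBH5 had a ratio of 1.99 in its start codon peak (60528944 to 60529534) and of -1.44 in its stop codon peak (60509012 to 60509186) in CON, and PSMD3 one of -1.19 in its start codon peak (22360153 to 22360502) and of -1.51 in its stop codon peak (22344751 to 22345075). The coding sequence peaks of FTO (chromosome 6, 31427720 to 31445131) and METTL3 (chromosome 7, 77673495 to 77673669) lay at 0.93 and -0.97 in CON, and the stop codon peak of METTL14 (chromosome 8, 105020731 to 105021005) at -0.75.

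**Figure D5:**
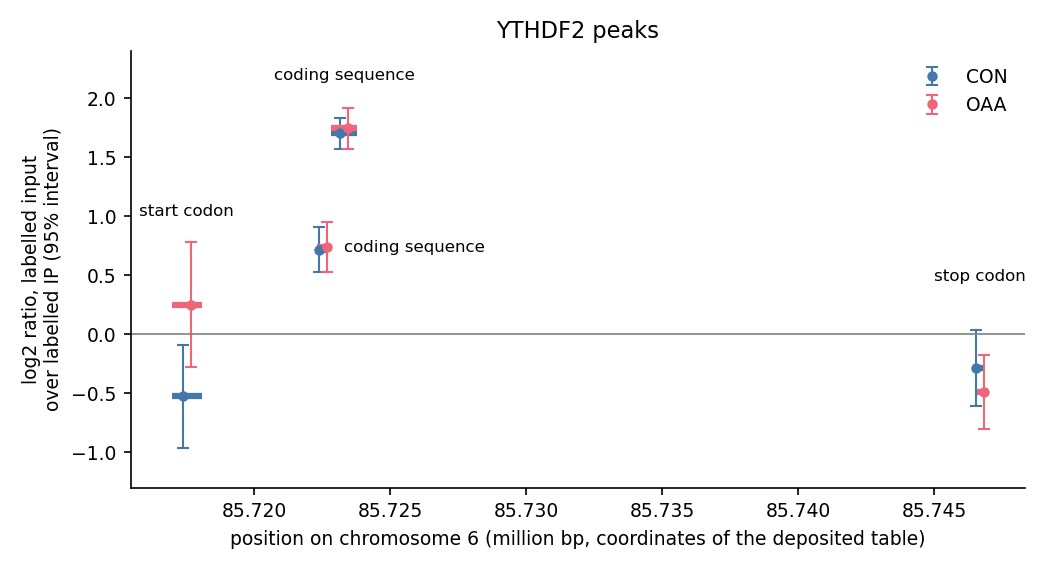
Log2 peak ratio (labelled input over labelled IP, y axis) of the YTHDF2 peaks along chromosome 6 (x axis, Mb in the deposited coordinates), in CON and OAA; horizontal bars span each peak, points are fitted ratios and error bars 95% intervals. The coding sequence peaks lie at 0.72 and 1.70 in CON and at 0.74 and 1.74 in OAA.

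Treated cells showed much the same landscape. For m6A enrichment in OAA, edgeR called 16024 of 23565 peaks, 7925 higher and 8099 lower, or 6399 and 9779 when scaled by library size alone. Over 23095 peaks tested in both treatments the ratios correlated at r = 0.926 (Spearman rho 0.937), 7162 peaks were called higher in both and 7289 lower in both, and 0 were called in opposite directions. MACROH2A1 had a scaled ratio of 155 (95% interval 53.04 to 754), CASKIN1 of 77.5 (13.8 to 3073) and the peak under PLEKHH3 and CCR10 of 63.9 (21.8 to 311). FKBP3, a nuclear isomerase (chromosome 1, 175331131 to 175332706, start codon), and DNTTIP1 had 371 and 283 counts in the libraries labelled input and 0 in those labelled IP, at least 10.1-fold and 7.65-fold higher against a floor of 3 counts per library. The lowest ratios were again in peaks under several genes: -6.03 for ZNF79 and RPL12, -6.02 for ABRAXAS1 and MRPS18C, -5.53 for LAMTOR3 and DAPP1, and -5.16 for both NAA20 with CRNKL1 and NSMAF with SDCBP.

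The lists in OAA gave 10 calls, none holding with an estimated correlation (adjusted p = 0.186 to 0.448 with an estimated correlation). Short-lived transcription factor mRNAs lay higher (median 0.79, 21 of 27 called higher, adjusted p = 0.000225), with BHLHE40 at 2.07. Ribosomal protein genes lay lower (median -1.83, 59 of 66, adjusted p = 5.57e-16), as did oxidative phosphorylation subunits (median -1.60, 37 of 40), mitochondrial mRNAs (-1.71, 7 of 8, or 8 adjusted over the list alone), cell cycle genes (-1.68, 20 of 24), proteasome subunits (-1.48, 21 of 24), fatty acid synthesis genes (-1.22, 9 of 12), hypoxia and glycolysis genes (-1.03, 12 of 18) and junction genes (-0.91, 12 of 18). NRF2 targets, antioxidant genes, were called in OAA (median -0.93, 10 of 16 lower, adjusted p = 0.0468), but not without OAA labelled-input library 1 or 3 (adjusted p up to 0.0676). Their difference between treatments was tested directly and did not pass (median -0.01, adjusted p = 0.741).

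Whether OAA altered m6A beyond expression was tested as the change of the peak ratio. No peak was called by edgeR. YTHDF2 as a whole differed by 0.05 ± 0.09 (log2, OAA over CON, SE), PSMD3 by 0.09 ± 0.10, ALKBH5 by 0.07, METTL3 by -0.09, METTL14 by -0.40 (unadjusted p = 0.0355) and FTO by -0.40 (unadjusted p = 0.0428), each with an adjusted p of 1.00. The YTHDF2 start codon peak had the largest difference of that gene's peaks (0.80 ± 0.33, unadjusted p = 0.0221, adjusted p = 0.999). EdgeR called 0 of 24145 peaks, with 1076 (4.46%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.974, limma-voom called 0, and DESeq2 called 1. With each culture as a block for its pair of libraries, edgeR called 1 peak against 0 without the block. Of 24931 peaks in the authors' deposited table, 0 had an adjusted p under 0.05, the smallest being 1.00, with 670 (2.69%) at an unadjusted p under 0.05; the test behind it is not given in the sources used here. The 95% interval reached a median of 0.62 log2 to either side, and simulated 1.5-fold, 2-fold and 4-fold changes were recovered at 20.9%, 74.6% and 97.0%. Those changes were placed only in peaks at or above the simulation's minimum mean CPM.

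The peaks with the smallest p for that change did not pass by edgeR. Those with a lower ratio in OAA included the stop codon peak of MRPL33 (chromosome 3, 111428906 to 111429080; -0.94), a 3' UTR peak under ARMC7 and NT5C (-0.84), a stop codon peak of CECR2 (-1.43) and a 3' UTR peak of the heparan sulfate carrier GPC1 (-0.82). Higher ratios were seen in coding sequence peaks of RIC8B (1.10) and RXRB, a retinoid X receptor (1.30), and in peaks under Tceal5 and TCEAL2 (1.51), CD2BP2 and MYL11 (1.16), and LACC1 and CCDC122 (1.60). The peak called with the culture block lies in a stop codon region of pro-pol, a retroviral polymerase gene (chromosome 5, 92187533 to 92188032; 1.48, adjusted p = 0.0204), and was called again without OAA labelled-IP library 3 (2.11, adjusted p = 8.47e-16). Leaving out CON labelled-IP library 3 gave 1 call, ARPC5 (-1.27, adjusted p = 0.0311), and leaving out OAA labelled-IP library 1 gave 1, ITGA3 (1.64, adjusted p = 0.000107). Unscaled labelled-IP counts of pro-pol were 2851, 2629 and 2617 in CON and 746, 705 and 2470 in OAA. Those of ARPC5 were 127, 157 and 306 in CON and 402, 451 and 433 in OAA. ITGA3 had 532, 525 and 400 in CON and 612, 163 and 167 in OAA. For each, the library left out was that of its group nearest the other treatment. Pro-pol, ARPC5 and ITGA3 lie outside the naming rule for this comparison and are named after their values were seen.

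Of the lists, camera called 1 in this change. Ribosomal protein genes had a lower ratio in OAA (median -0.16, 59 of 67 below 0, adjusted p = 0.00134; adjusted p = 0.968 with an estimated correlation), with RPL14 at -0.42, RPL35A at 2.19 ± 1.16 (SE) and the RPL9 identifiers at 0.90 and -0.42. No member was called over all genes or adjusted over the list alone. The direction turned without CON labelled-input library 1 (median 0.04, adjusted p = 0.0406), and the call was lost without OAA labelled-input library 1 (-0.11, adjusted p = 0.0992), CON labelled-IP library 1 (-0.11, adjusted p = 0.307) or OAA labelled-IP library 1 (-0.08, adjusted p = 0.876). The number of called lists was 3 without CON labelled-input library 2 and 2 without OAA labelled-input library 3 or OAA labelled-IP library 3. Interferon-stimulated genes had the highest median (0.29, 10 of 12 above 0) and did not pass (adjusted p = 0.162). Aryl hydrocarbon receptor targets held the 1 gene called adjusted over the list alone in any treatment comparison, IDO1, an enzyme of tryptophan breakdown, at -2.85 (0.0467 adjusted over the list alone, 1.00 over all genes).

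Peak counts of the libraries labelled IP were last compared between OAA and CON. A 5' UTR peak of env, a retroviral envelope gene (chromosome 3, 10663073 to 10663297), rose by edgeR from 650 ± 37.4 to 881 ± 110 CPM (SD, n = 3), a log2 change of 0.44 (95% interval 0.29 to 0.59, adjusted p = 0.0341), and DESeq2 also called 1 peak, this one. Copies of such genes share reads, so its position is uncertain. Next by p, and not passing in this fit, came MergePeak_8387 at 0.68 (chromosome 15, 66866625 to 66867074, adjusted p = 0.0841). It is listed under 1 gene, which has no symbol, and in no annotated part of it. The start codon peak of ARPC5, a subunit of the actin-nucleating complex, followed at 0.97 (chromosome 9, 124845375 to 124848086, adjusted p = 0.141). Pro-pol came after it (-1.17, adjusted p = 0.223). TUBB2B (0.31), MISP (1.03), the peak under HCRTR1 and PEF1 (0.63), KBTBD6 (-0.97), HDDC3 (-0.63) and ETV3 (-1.12) completed the 10. EdgeR called 1 of 20098 peaks, with 779 (3.88%) at an unadjusted p under 0.05, or 660 to 1789 with a library left out. The env peak was not called without CON labelled-IP library 1 (0.46, adjusted p = 0.578), 2 (0.47, 0.182) or 3 (0.39, 0.874), nor without OAA labelled-IP library 1 (0.40, 0.142) or 2 (0.37, 1.00).

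Without OAA labelled-IP library 3 the same comparison gave 50 peaks, 40 higher and 10 lower in OAA. Among the 40 were 11 peaks of ribosomal protein genes, and others lay in VIM, an intermediate filament (0.34), the glycolytic enzyme ALDOA (0.38), the desaturase SCD (0.46), ARPC5 (0.95) and env (0.54). The lowest of the 10 was pro-pol at -2.05, and GCLM, of glutathione synthesis, was at -0.31. These genes were named after their values were seen, from 1 of 6 fits that leave out a library. Library 3 lay beyond all CON libraries in the same direction in 10 of the 50 peaks.

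The change of the peak ratio shares its libraries with the labelled-input comparison. Over 9097 genes tested in both, 0 were called in both, and 85 had an unadjusted p under 0.05 in both, against 105 to 147 in 20 simulated draws with no effect and 16.3 for independent lists. The differences correlated across genes at r = 0.439, against 0.429 to 0.519 in the draws, with a covariance of 0.0573 against 0.0377 to 0.0450. The draws hold the shared libraries but no effects, the controls were too few to split, and the higher covariance is not read as a shared effect.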

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

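The tests of this part were chosen before the result was seen, except the fits with a library left out. The 1 result marked here is the ribosomal protein list, whose peak ratio differed between the treatments by a test of the difference itself (median log2 -0.16 in OAA against CON, camera adjusted p = 0.00134). With an estimated correlation the list was not called (adjusted p = 0.968 with an estimated correlation). Its median ratio was -1.65 in CON and -1.83 in OAA, and 59 of 67 genes lay below 0 in the difference. Per culture it was -1.17, -1.92 and -1.98 in CON and -2.04, -1.90 and -1.56 in OAA, so the treatments overlap. The labelled-input libraries of the cultures with the highest values, CON culture 1 and OAA culture 3, also had the highest share of mitochondrial reads, 0.343% and 0.379% against 0.258% to 0.283% in the others. CON culture 1 has the highest value of all: without its labelled-input library the median was 0.04 and the direction turned (adjusted p = 0.0406). The number of lists called in this change was reached or passed in 8 of 10 splits of the cultures.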

How the results depend on the processing

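Alternatives here were chosen before the result was seen, except those said in the processing part to have been added later or not planned. For results that did not hold, the cause was not tested. In labelled input, 0 calls became 1 with DESeq2 and 0 to 1 with a library left out (1 without OAA library 1). For m6A enrichment in CON, 16242 calls became 6975 summed per gene, where fewer features are tested, 10584 at 2-fold, and 14954 to 15810 with a library left out. For m6A enrichment in OAA, 16024 became 6830 summed per gene and 14606 to 16046 with a library left out. For the change of the ratio, 0 calls became 1 with DESeq2, 1 with the culture block, 1 without both libraries of OAA culture 3, and 0 to 1 with a library left out. In labelled IP, 1 call became 0 with library size only, summed per gene or at 2-fold, 3 with limma-voom, 4 with no count filter and 4 with the replicate block, and 0 to 50 with a library left out. In FPKM, 0 calls became 1 without the FPKM filter and stayed 0 with a library left out.

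An estimated correlation left 0 lists in each of the 5 list comparisons. Fry left 0 for FPKM, labelled input and the change, and gave 17 in CON and 19 in OAA. With the block, the number of called lists went from 5 to 4 in FPKM, where cholesterol synthesis was lost (adjusted p = 0.0568), and stayed at 3, 9, 10 and 1 in labelled input, CON, OAA and the change. With a library left out it ran from 0 to 5 in FPKM, 0 to 6 in labelled input, 9 to 10 in CON, 10 to 11 in OAA and 0 to 3 in the change. The list of cytosolic ribosomal proteins reversed without CON labelled-input library 1, in labelled input (adjusted p = 3.57e-09) and in the change (adjusted p = 0.0406). With a library left out its adjusted p ran from 1.63e-10 to 0.375 in labelled input and from 9.59e-13 to 0.876 in the change. In labelled IP, where replicate numbers do not pair the treatments, the peaks added by the replicate block were pro-pol (adjusted p = 0.00766), MergePeak_8387 (0.0209) and ARPC5 (0.0217). With these, the lost list and the 1 peak in the change of the ratio, the block changed no other call of a list or named feature. For m6A enrichment in CON it gave 16065 calls, and for m6A enrichment in OAA 16064. The 0 genes called in both the labelled-input comparison and the change stayed 0 with the block.

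Scaling by RLE or upper quartile moved the median of all peaks little, the largest shift being 0.06 log2. Of the single features, 363 comparisons with an alternative stayed the same for the change, 320 for FPKM, 249 for labelled input, 121 for labelled IP, 222 for CON and 221 for OAA, against 4, 4, 2, 6, 0 and 0 that moved or weakened and 1, 0, 2, 13, 0 and 1 that became stronger. Staying the same means that sign and call, or lack of a call, were kept. For the change, FPKM and labelled input no feature was called, so there it means only a kept sign and no call. Planned FPKM alternatives were not run for labelled input, since those columns belong to libraries labelled IP. The change has the widest 95% interval, with a median of 0.62 log2 to either side, and depth was not varied to see what it limits.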

Other observations

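The tests of the peaks by position were chosen after the result was seen. The share of peaks called higher or lower, under TMM scaling, is given here by where they lie in the mRNA, and the classes were not tested against each other. Of 5681 stop codon peaks tested in CON, 2671 (47.0%) were called higher and 1815 (31.9%) lower, while of 4408 peaks in the 3' UTR, 1192 (27.0%) were higher and 1851 (42.0%) lower. Start codon peaks had 1157 of 4579 (25.3%) higher and 1633 (35.7%) lower, 5' UTR peaks 555 of 1586 higher and 375 lower, and coding sequence peaks 1899 and 2049 of 5593. Peaks that cover both start and stop codon had 121 of 194 (62.4%) higher and 52 (26.8%) lower, and peaks with no annotated part 571 of 1325 (43.1%) higher and 301 (22.7%) lower. If the titles hold, the lower side is the enriched one. The median log2 ratio of stop codon peaks was 0.30 ± 0.02 in CON and 0.29 ± 0.04 in OAA, and that of 3' UTR peaks -0.28 ± 0.01 and -0.26 ± 0.02 (SD, n = 3). Over all classes the difference between the treatments lay between -0.03 and 0.03, and 3 against 3 cultures are too few for an exact permutation to call any.

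More reads in peaks in the libraries labelled input is a pattern that was seen first, and both of its tests were written after. If the titles IP and input had been exchanged against the library codes, mRNAs usually rich in m6A would have the higher ratio in every culture. The median of the short-lived transcription factor list exceeded that of the ribosomal list by at least 1.86 log2 in each of the 6 cultures, as an exchange predicts. Whether a difference in library depth adds to the excess of reads cannot be told: totals outside peaks are not used here, and the correlation of scaled ratios between CON and OAA (r = 0.926) does not bear on depth, which scaling removes. If the titles held, mRNAs usually rich in m6A would have the lower ratio. The differences of 1.86 to 2.78 log2 therefore argue against the titles, for these lists. The deposited log2 ratios, above 0 in 99.9% of peaks in CON and 99.8% in OAA, follow labelled input over labelled IP. Only the people who made the libraries can correct the labels.

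OAA culture 3 stood apart from OAA cultures 1 and 2 in both of its libraries. On the first principal component it lay at 13.3 against -8.66 and -6.56 in FPKM (39.4% of variance), and at 7.94 against -6.43 and -4.89 in labelled input (29.2%). Its deviations in the libraries labelled IP and input correlated across genes at r = 0.454, against 0.010 to 0.259 in the other cultures, and that value speaks against a fault of 1 library alone, a test written after. Gene length bias could not be told from its absence: Spearman rho with genomic span, a loose stand-in for mRNA length, was 0.372 in FPKM and 0.169 in labelled input, a test whose idea came from the same data. Culture 3 also had the highest mitochondrial share of all cultures, at 0.379% in labelled input, 1.12% in labelled IP and 12.3% of FPKM. Its mitochondrial mRNAs lay 0.54 log2 above those of OAA cultures 1 and 2 in labelled input and 0.06 above in FPKM. Other lists differed in sign between the library sets. Against OAA cultures 1 and 2, ribosomal proteins lay at -0.16 in FPKM and 0.15 in labelled input, and oxidative phosphorylation at -0.13 and 0.14. Some kept their sign, such as short-lived transcription factor mRNAs (-0.13 and -0.04). A true difference between cultures and a shared step before the RNA was divided may both give the shared part of the deviations. The value r = 0.454 does not part them.

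The OAA minus CON differences of the libraries labelled IP and of those labelled input correlated across 5661 genes at r = 0.235. Genes are not independent replicates, and 5 of 10 splits of the 6 cultures into 3 and 3, the real one included, gave a correlation as high, up to 0.473. Gene length bias could not be decided (rho -0.133 in FPKM and -0.135 in labelled input). For OAA cultures 1 and 2 alone against CON, rho was -0.314 in FPKM and -0.199 in labelled input. The correlation may therefore reflect which cultures share a side, as 5 of the 10 splits reach it, and cannot be ascribed to OAA.

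The same splits were made for every comparison, a test fixed before the result was seen. With 3 against 3 libraries there are 10 splits, so the share that reaches the real value cannot be under 0.1. Features at an unadjusted p under 0.05 reached the real number in 4 splits for labelled input (453, highest other 859), 5 for the change of the ratio (1076 and 1638), 6 for labelled IP (779 and 2271) and 6 for FPKM (356 and 2079). For the ratios only the real split, 1 of 10, reached the calls in CON (16242, highest other 0) and in OAA (16024 and 0). Every other split of these libraries puts both labels into each group, so the absence of calls was fixed in advance. It is no evidence on chance, and the same mixing holds for the lists in CON and in OAA. For called lists the number of splits was 1 in FPKM (5, highest other 4), 5 in labelled input (3 and 6), 1 in CON (9 and 8), 1 in OAA (10 and 8) and 8 in the change (1 and 6). The split that puts OAA culture 3 with CON cultures 1 and 2 called 9 genes in labelled input, 195 peaks in labelled IP and 1 gene in FPKM.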
